A study of Solanum lycopersicum with 14 samples.

How the data were processed

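Total RNA from fruit pericarp, the fleshy wall of the fruit, of tomato (Solanum lycopersicum) was sequenced from M82, a red-fruited wild-type cultivar, and n3122, a yellow-fruited mutant in the M82 background. The 14 libraries fell into 7 groups of 2 libraries, M82 at 35, 47 and 54 DPA and n3122 at 35, 47, 54 and 60 DPA, where DPA is the fruit age as the labels give it, in this field days post anthesis. Per the labels' protocols, the plants grew in a greenhouse, RNA was extracted with a column kit and libraries were made with the Illumina TruSeq RNA kit. No label says whether the 2 libraries of a group came from separate plants, so p-values may measure only technical spread.

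Per the submitters' processing notes, CASAVA, TopHat2 version 2.0 and Cufflinks were used. The genome build and the gene annotation are not given in the sources used here. The deposited values are 4 tables, each comparing one n3122 group with one M82 group over 34725 genes. Per the file headers, each table gives one FPKM value per gene and group (fragment numbers scaled to transcript length and library size), the log2 fold change between both FPKM values, a test statistic, a p-value and a q-value. The FPKM of a group is the authors' single value for its libraries together, and no value per replicate was given. The test statistic is a score that the authors deposited per gene, at 0 with a p-value of 1 for genes that were not tested. The p-values and q-values are the authors' own, and each q-value equalled the Benjamini-Hochberg adjustment of the p-values over the genes tested, to within 5.26e-07. The smallest p-value in each table was 5e-05, shared by 285 genes at 35 DPA and 2494 genes at 54 DPA, so genes at this floor cannot be ranked by p. In the table of n3122 at 60 DPA against M82 at 47 DPA the sign of the statistic was the opposite of that of the fold change, so directions were taken from the FPKM columns, whose headers name the groups. M82 at 47 DPA stands in 2 tables, and its FPKM values differed between them by a nearly constant ratio of 0.960 (SD 0.00119 over 17296 genes). The tables were therefore taken as scaled separately, and each call and fold change between genotypes comes from one table. Some values set tables side by side: the fold changes of M82 from 35 to 47 DPA, taken between tables with their median set to 0, the differences between fold changes of different comparisons, and rank correlations between groups.

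With no replicate values, no test of single genes was made, and values carry no error. A gene was called where the authors' q-value was at or under 0.05. The fold change printed is log2((n3122 + 1) / (M82 + 1)) from the FPKM values, with a pseudocount of 1 FPKM, which understates the change of low genes. The number of reads per library is unknown, since the files give no counts, so no interval from counting is given. A listing at 0 can be a failed estimate: at 54 DPA, 9 genes were listed at 0 in one group and at 1000 FPKM or more in the other, and none of the 9 was tested. Such genes were called in 1 of 7 cases at 35 DPA, in 0 of 7 at 47 DPA and in 2 of 8 for n3122 at 60 DPA against M82 at 47 DPA. For such genes no fold is given. FPKM totals per group ran from 1268273 to 1456313, and the most abundant gene of M82 at 54 DPA alone took 25.2% of its group's total, against 9.03% in n3122, where its value of 119477 FPKM was also that of another gene. At 35 DPA this gene was listed at 183219 FPKM in M82 and at 0 in n3122, so its shares are uncertain. The median log2 fold change of genes with at least 1 FPKM in both groups was -0.01 at 35 DPA, -0.03 at 47 DPA, -0.05 at 54 DPA and 0.00 for n3122 at 60 DPA against M82 at 47 DPA.

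The tables name genes by identifier and give no symbols or descriptions. The reference table at hand (assembly SLM_r2.1) holds none of these identifiers. The gene lists therefore rest on pairs of symbol and identifier written down from general knowledge of tomato genetics before the data were examined, as were the groups, the list tests, the rule for naming genes and all alternatives but one. Most tests weighed at the close were chosen later, as said there. Each pair was then checked against the reference table, asking whether a gene under that symbol, a synonym or another name lies on the same chromosome and within 5% of the same relative place. Where several genes carried such a name, the nearest was taken. Of 165 listed genes, 135 met both, 25 had a symbol that the reference table lacks, and 5 lay elsewhere and were dropped. Of the 135, 105 were reached by the symbol itself, 18 by a synonym in the reference table, and 12 only by another name looked up in that table afterwards, so for these the check is weaker: DXS1, E8, PE2, PE3, POR3, RBCS1, RBCS2, CAB1, PALb, PALd, CHI and F3primeH. The reference table gives the symbol ACO3 to the gene reached for E8, and the gene named ACO3 in the text was reached by a synonym. The check cannot tell a gene from its close neighbours. Among the genes named in the text, NR, RCA, PAO, PPH, POR1, APRR2, GGPS3, CCD4B, CHIL, PALc, SUSY, GAME31, CYP86A69 and MIXTA were not checked in this way. Members of one family with near-identical sequences, such as the CAB, RBCS and GAME genes, can share reads, so single members are uncertain.

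The 13 lists cover the precursor (MEP) pathway of carotenoids, carotenoid synthesis to lycopene, cyclization and xanthophyll synthesis, carotenoid cleavage and abscisic acid (ABA) synthesis, ethylene synthesis, ethylene perception and signalling, ripening regulators with ethylene-responsive ripening genes, cell wall and softening, chlorophyll metabolism and photosynthesis, aroma volatiles and sugar metabolism, phenylpropanoid and flavonoid synthesis, steroidal glycoalkaloid synthesis, and cuticle and epidermis as another cell type of the pericarp. Per list, direction and comparison, the called members were set against all other tested genes with Fisher's exact test, two-sided, and the 104 p-values were adjusted by Benjamini-Hochberg. Genes are not independent replicates, so these p-values describe the lists within these libraries. Beside the calls over all genes tested, the calls adjusted over the list alone were counted from the authors' p-values. Another 5 lists that select genes by words in a description were not run, because the files give no descriptions. The genes named were, per comparison, the 6 with the largest positive and the 6 with the largest negative log2 fold change among called genes with at least 10 FPKM in the higher group, up to 3 called members of each list by size of change, and always EIN2 (Solyc09g007870), PSY1 (Solyc03g031860), RIN (Solyc05g012020), NOR (Solyc10g006880), ACS2 (Solyc01g095080), ACS4 (Solyc05g050010), ACO1 (Solyc07g049530), NR (Solyc09g075440), E4 (Solyc03g111720), E8 (Solyc09g089580), PG2A (Solyc10g080210) and SGR1 (Solyc08g080090). Other list members named as examples were chosen after their values were seen. The values of some list members are not reported here. Of the 35 different genes among the 6 largest per direction, 3 were on a list, and at most 4 of the rest are given by identifier.

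The list test was tested on simulated data before use, with the 18751 genes tested at 47 DPA and lists of 15 genes of which 9 were lower. In 40 rounds 160 of 160 such lists were found. The 9 lower calls were fixed, so this shows that the test runs, not how small a change it finds. Of 800 tests with nothing planted, 4 (0.5%) passed. These include tests for higher genes on the lists planted lower, which could hardly pass. Calls were drawn gene by gene, so the 0.5% is not an error rate for genes that change together. Alternatives tried were a q-value of 0.01, a minimum absolute log2 fold change of 1, a filter of 1 FPKM in either group, a pseudocount of 0.1, a median log2 fold change set to 0, the other table for M82 at 47 DPA and, chosen after seeing the data, lists of checked names alone. Other count-based tests, leaving out a replicate and blocking by replicate number need values per replicate and were not run. The computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.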

Results

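Transcript levels were measured by RNA sequencing in the fruit pericarp of the red-fruited tomato M82 and its yellow-fruited mutant n3122, with 2 libraries per group. M82 was sampled at 35, 47 and 54 DPA and n3122 at 35, 47, 54 and 60 DPA. The authors compared both genotypes at 35, 47 and 54 DPA, and n3122 at 60 DPA with M82 at 47 DPA. The question, as the series title puts it, is how the transcriptomes of red and yellow fruit differ. Levels are the authors' FPKM per group, the calls are those of a q-value at or under 0.05 in the authors' deposited tables, and no values per replicate or sequencing depths were given, so no SD stands beside a level. Higher and lower refer to n3122 relative to M82 throughout, on the scale of log2(FPKM + 1).

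The genotypes differed least at 35 DPA and most at 54 DPA by number of genes called. With a minimum log2 fold change of 1 the numbers at 47 and 54 DPA were close, 3190 and 3291 genes. The authors' deposited tables called 601 of 18541 tested genes (3.24%) at 35 DPA, 355 of them higher and 246 lower. At 47 DPA they called 4409 of 18751 genes (23.5%), 2569 higher and 1840 lower, and at 54 DPA 5574 of 18796 genes (29.7%), 3409 higher and 2165 lower. For n3122 at 60 DPA against M82 at 47 DPA, the authors' deposited table called 2824 of 18823 genes (15%), 1493 higher and 1331 lower.

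**Figure D1:**
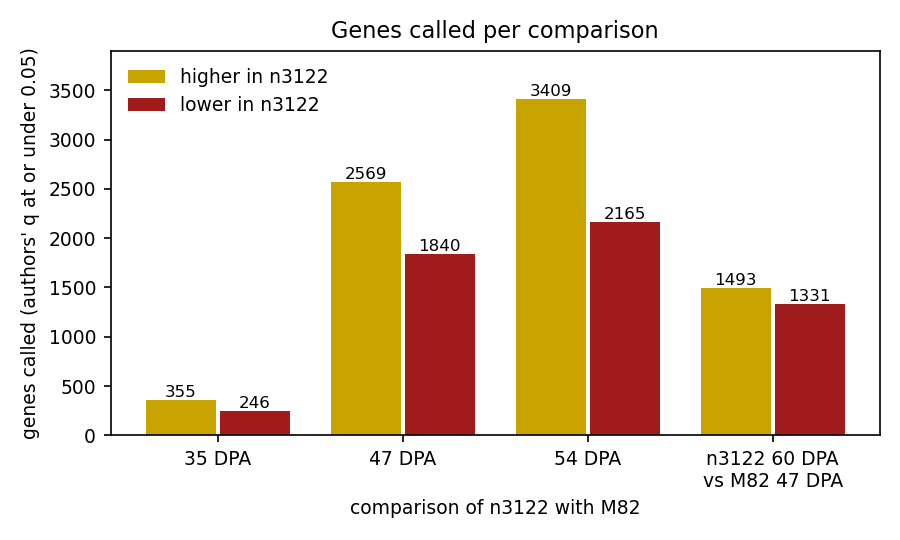
Number of genes called higher and lower in n3122 in each of the 4 comparisons, from the authors' q-values. Calls number 601 at 35 DPA, 4409 at 47 DPA, 5574 at 54 DPA and 2824 for n3122 at 60 DPA against M82 at 47 DPA, with more genes higher than lower in each.

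EIN2 (Solyc09g007870), the central transducer of the ethylene signal, was lower in n3122 in each of the 4 comparisons. Its FPKM was 48.9 in M82 and 3.75 in n3122 at 35 DPA, 35.0 and 2.50 at 47 DPA, and 40.8 and 2.91 at 54 DPA, log2 fold changes of -3.39, -3.36 and -3.42. In n3122 at 60 DPA it stood at 1.95 against 33.6 in M82 at 47 DPA (log2 fold change -3.55). The q-values for EIN2 in the authors' deposited tables were 0.00325, 0.000521, 0.000377 and 0.000943, the smallest that each table holds. The labels name no mutated gene.

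Of the 12 genes named whatever their values, 3 were called at 35 DPA (EIN2 and E4 lower, SGR1 higher), all 12 were lower at 47 DPA, and ACO1 alone was not called at 54 DPA. RIN, a MADS-box regulator required for ripening, had 2.26, 733 and 977 FPKM in M82 at 35, 47 and 54 DPA, and 2.66, 7.23, 28.3 and 364 in n3122 at 35, 47, 54 and 60 DPA. PSY1, the fruit phytoene synthase that opens the carotenoid pathway, had 143, 4270.2 and 3034 FPKM in M82 and 113, 88.0, 129 and 644 in n3122. ACS4, a ripening-related synthase of the ethylene precursor, had 0.920, 105 and 122 FPKM in M82 and 1.07, 1.24, 10.5 and 144 in n3122. E4, an ethylene-responsive ripening gene, had 112, 4672 and 2477 FPKM in M82 and 22.6, 33.8, 45.6 and 48.2 in n3122. The ages come from tables scaled separately and differences between ages were not tested.

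**Figure D2:**
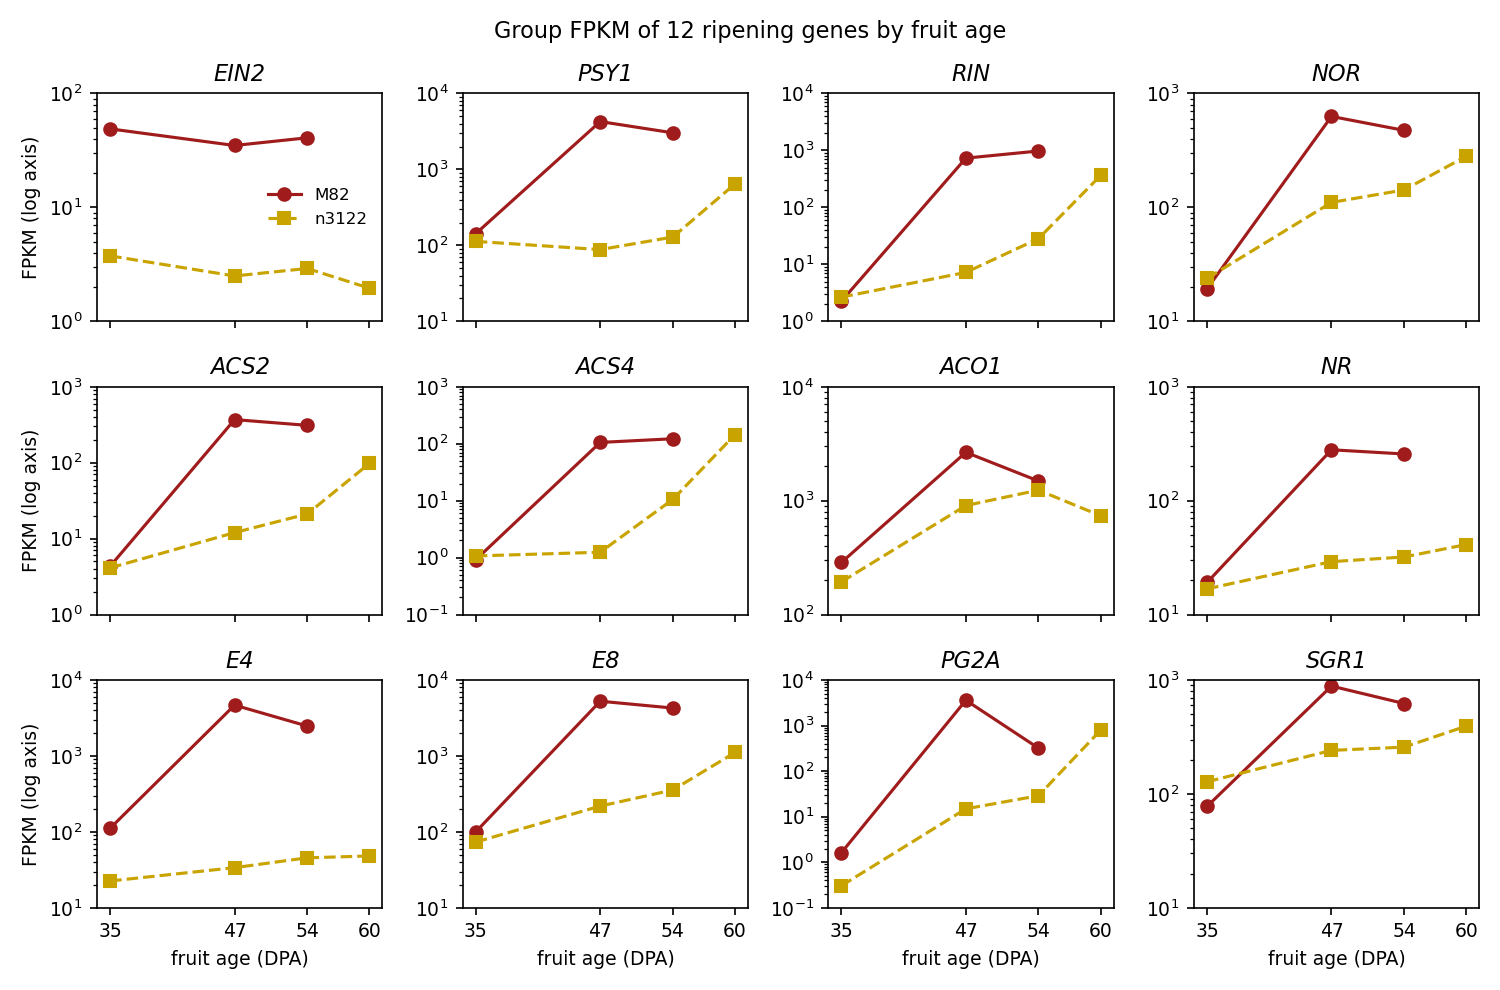
FPKM per group (log axis) against fruit age in DPA for the 12 genes named whatever their values, M82 as circles with solid lines and n3122 as squares with dashed lines; points are the authors' single value per group and carry no error. RIN in n3122 goes from 2.66 FPKM at 35 DPA to 364 at 60 DPA, while EIN2 in n3122 stays between 1.95 and 3.75.

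At 35 DPA, many genes of photosynthesis were higher in n3122 and a few genes of the ethylene pathway were lower. CAB3C and CAB1, light-harvesting chlorophyll-binding proteins, had 68.8 and 256 FPKM in n3122 against 23.2 and 104 in M82 (log2 fold changes 1.53 and 1.29). Besides EIN2, the ethylene-responsive E4 was lower, at 22.6 against 112 FPKM (log2 fold change -2.26). Each of these had a q-value of 0.00325 in the authors' deposited table, the smallest it holds.

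Of 20 tested genes of chlorophyll metabolism and photosynthesis, 10 were higher and none lower at 35 DPA, and 19 were higher when adjusted over the list alone (Fisher's exact test on the 10, two-sided, adjusted p = 9.46e-11). They included RCA, the Rubisco activase gene (log2 fold change 0.99), the Rubisco small subunit genes RBCS1 and RBCS2 (0.94 and 0.92), CAB4, CAB6A, the photosystem II protein gene PSBP, and SGR1, which acts in chlorophyll breakdown (77.7 FPKM in M82 and 128 in n3122). Of 7 genes of cyclization and xanthophyll synthesis, LCYE, the lycopene epsilon-cyclase, and ZEP, the zeaxanthin epoxidase, were higher, with log2 fold changes of 1.02 and 0.62, and 4 were higher when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0277). Of 6 genes of carotenoid synthesis to lycopene, PDS, the phytoene desaturase, was higher at 86.2 against 56.2 FPKM, and 2 were higher when adjusted over the list alone (Fisher's exact test, adjusted p = 0.30). PSY1 was not called, with 143 FPKM in M82 and 113 in n3122.

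Of 15 genes of ethylene perception and signalling, 3 were lower at 35 DPA and none higher, the same numbers when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00539). Beside EIN2 these were ETR6, an ethylene receptor gene (9.83 FPKM in M82 and 3.98 in n3122), and EBF1, an F-box gene of ethylene signalling (37.0 and 17.6). The list test was not run without EIN2, so its p-value rests partly on that gene. Of 11 genes of ethylene synthesis, ACO5 and ACO6, oxidases of the last step, were lower (log2 fold changes -1.16 and -0.69), and 3 were lower when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0331). NR, another ethylene receptor gene, was not called, at 19.1 FPKM in M82 and 16.8 in n3122, and neither were ACS2 (4.34 and 4.12) or ACO1 (287 and 194).

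The other lists held few calls at 35 DPA. Of 16 ripening regulators and ethylene-responsive genes, E4 was lower and TAG1, a MADS-box gene, higher (43.2 FPKM in M82 and 68.8 in n3122), the same numbers adjusted over the list alone, while RIN, NOR (19.3 and 23.8 FPKM) and E8 (100.3 and 73.5) were not called. MAN4, an endo-mannanase gene, was higher among 13 cell wall genes (0.308 FPKM in M82 and 6.19 in n3122), with 1 higher and 1 lower adjusted over the list alone; PG2A, the fruit polygalacturonase, was not called at 1.63 and 0.306 FPKM. CHS2, a chalcone synthase gene, was higher among 15 genes of phenylpropanoid and flavonoid synthesis (log2 fold change 0.66), and 1 was higher adjusted over the list alone. AADC1A was lower among 10 genes of aroma volatiles and sugar metabolism (log2 fold change -1.04), with 1 higher and 2 lower adjusted over the list alone, and GAME18 was lower among 9 genes of steroidal glycoalkaloid synthesis (log2 fold change -1.28), again 1 adjusted over the list alone. No call fell on the 11 precursor pathway genes, the 7 of carotenoid cleavage and ABA synthesis or the 6 of cuticle and epidermis; adjusted over the list alone, these numbers were 0, 1 lower and 2 higher. None of these 8 lists or of the lycopene list passed the list test. The calls on the cyclization and ethylene synthesis lists were lost at a q-value of 0.01 (Fisher's exact test, adjusted p = 0.210 and 0.223) and with a minimum log2 fold change of 1 (0.171 and 0.207).

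At 47 DPA, M82 expressed many ripening genes at high levels. Many of these were lower in n3122, some of them far lower, while most photosynthesis genes were higher. PL, a pectate lyase gene of fruit softening, had 1832 FPKM in M82 and 4.21 in n3122 (log2 fold change -8.46), and PG2A had 3598 and 14.9 (-7.82). RIN was at 733 against 7.23 FPKM (-6.48), PSY1 at 4270.2 against 88.0 (-5.58) and E4 at 4672 against 33.8 (-7.07). RBCS2 went the other way, with 7.87 FPKM in M82 and 100.1 in n3122 (3.51). All of these had a q-value of 0.000521 in the authors' deposited table, the smallest it holds.

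Of 16 ripening regulators and ethylene-responsive genes, 10 were lower at 47 DPA and none higher, also when adjusted over the list alone (Fisher's exact test, two-sided, adjusted p = 6.44e-06). They included NOR, a NAC transcription factor gene (629 FPKM in M82 and 111 in n3122), CNR (262 and 37.0), AP2A (359 and 38.1) and E8 (5258 and 219). TAGL1, with 226 and 144 FPKM, and FUL2, with 227 and 154, were not called. Of 14 cell wall genes, 9 were lower and 1 higher, the same adjusted over the list alone (Fisher's exact test, adjusted p = 1.56e-05). Beside PL and PG2A, the expansin gene EXP1 (859 FPKM in M82 and 13.7 in n3122), CEL2 (265 and 1.66) and MAN4 (1135 and 31.5) were lower. PMEU1, a pectin methylesterase gene, was the one higher, at 8.96 and 147 FPKM.

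Carotenoid genes up to lycopene were lower together at 47 DPA. Of 6 tested, 5 were lower, also adjusted over the list alone (Fisher's exact test, adjusted p = 0.000432): PSY1, PDS, ZDS, CRTISO and Z-ISO, the zeta-carotene isomerase gene, which had 2172 FPKM in M82 and 38.4 in n3122. ZDS, the zeta-carotene desaturase gene, had a log2 fold change of -1.20. PSY2 was not called, at 19.8 and 13.7 FPKM. In the precursor pathway 5 of 11 were lower, also adjusted over the list alone (Fisher's exact test, adjusted p = 0.0125), among them GGPS2, a geranylgeranyl diphosphate synthase gene (92.3 FPKM in M82 and 1.71 in n3122), DXS1, which encodes the first enzyme (186 and 96.0), GGPS3 (log2 fold change -1.79) and CMK (-1.39). The median of the precursor list was -0.55, above that of 5.01% of random lists of like expression. Of 8 genes past lycopene, LCYE and ZEP were higher (log2 fold changes 1.52 and 0.91) and the beta-carotene hydroxylase genes CRTRB1 and CRTRB2 lower (-1.45 and -0.97), the same adjusted over the list alone; that list did not pass in either direction. Of 7 genes of carotenoid cleavage and ABA synthesis, 3 were higher and 1 lower, the same adjusted over the list alone, and the list did not pass (Fisher's exact test, adjusted p = 0.185 for higher). The ABA 8'-hydroxylase genes CYP707A1 and CYP707A2 went opposite ways, with log2 fold changes of 1.58 and -1.35, and the cleavage dioxygenase gene CCD4B was higher (3.03).

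Both ethylene lists passed the list test for lower genes at 47 DPA. Of 15 genes of perception and signalling, 7 were lower and 1 higher, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.00178). These were EIN2, the receptor genes NR (279.7 FPKM in M82 and 29.1 in n3122), ETR4 (299 and 55.9), ETR6 and ETR7, the kinase gene CTR1, and EBF1 (159 and 31.3), while the transcription factor gene EIL2 was higher (log2 fold change 0.83). Of 11 genes of ethylene synthesis, 5 were lower and 2 higher, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.0125). The median log2 fold change of the synthesis list was -0.30, above that of 17.0% of random lists of like expression. The synthesis list as a whole was thus not clearly lower than such genes. ACS2 had 369 FPKM in M82 and 12 in n3122, ACS4 105 and 1.24, and ACO1 2657 and 906. ACO3 was lower with a log2 fold change of -2.86, whereas ACS6 was higher at 6.94 and 55.6.

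Many genes of flavonoid and aroma synthesis were lower at 47 DPA. Of 16 genes of phenylpropanoid and flavonoid synthesis, 9 were lower and none higher, and 10 were lower adjusted over the list alone (Fisher's exact test, adjusted p = 5.76e-05). CHS1 and CHS2, chalcone synthase genes, had 339 and 289 FPKM in M82 and 0.195 and 12.5 in n3122, CHIL, a chalcone isomerase-like gene, had 254 and 19.8, and MYB12, a flavonoid regulator gene, had 50.2 and 10.02. Of 11 genes of aroma volatiles and sugar metabolism, 6 were lower and 3 higher, with 6 lower and 4 higher adjusted over the list alone (Fisher's exact test, adjusted p = 0.00178). LOXC, a lipoxygenase gene of volatile synthesis, had 393 FPKM in M82 and 0.428 in n3122, AAT1, an acyltransferase gene, 1866 and 20.5, and the invertase gene TIV1 2028 and 226. AADC1A, LIN6 and SUSY were the members higher.

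Of 20 genes of chlorophyll metabolism and photosynthesis, 14 were higher and 4 lower at 47 DPA, the same adjusted over the list alone (Fisher's exact test, adjusted p = 7.10e-07 for higher). CAB7 had 99.7 FPKM in M82 and 433 in n3122, CAB8 20.9 and 154, and POR1, a protochlorophyllide oxidoreductase gene, 1.10 and 19.6. The 4 lower were SGR1 (885 and 241), PAO and PPH, which act in chlorophyll breakdown, and the regulator gene APRR2 (log2 fold change -2.87). Of 9 genes of steroidal glycoalkaloid synthesis, 5 were higher and none lower, also adjusted over the list alone (Fisher's exact test, adjusted p = 0.0162), among them GAME4 (0.520 FPKM in M82 and 6.01 in n3122), GAME12 (5.29 and 37.7) and GAME11 (18.4 and 44.6). Of 6 cuticle and epidermis genes, listed for another cell type of the pericarp, CD1, a cutin synthase gene, was higher at 0.484 against 42.0 FPKM, 1 also adjusted over the list alone, and the list did not pass (Fisher's exact test, adjusted p = 0.898). CD1 also fell with age, from 289 FPKM at 35 DPA to 0.484 at 47 DPA in M82. In n3122 it fell from 447 to 42.0, so it may not reflect cell type alone. CYP86A69, at 0.0503 FPKM in M82 and 16.1 in n3122, and SHN3, listed at 0 in M82 and at 3.18 FPKM in n3122, were not called. Nor were CD2, CER6 and MIXTA, with log2 fold changes of 0.27, -0.01 and -0.53, so the list was split. The median log2 fold change of this list was 0.29, 1.17, 1.26 and 0.83 across the 4 comparisons, above that of 99.0%, 99.7%, 99.3% and 99.5% of 10000 random lists of equal size and like expression, a description beside the list test. Other lists lay as near either end or nearer in each comparison, so the cuticle list did not stand out. The photosynthesis list lay above 100%, 100%, 100% and 99.8% of random lists across the 4 comparisons. At 35 DPA the precursor pathway, with no call, lay above 99.45% of random lists, and ethylene perception and signalling above 0.19%.

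Among genes without a name in the files, Solyc01g091170 was among the most increased at 47 DPA, with 0.914 FPKM in M82 and 386 in n3122, and Solyc08g066240 the most decreased, with 2539 and 0.371 FPKM (log2 fold changes 7.66 and -10.86). Solyc02g077430 was higher (6.34) and Solyc01g088400 lower (-8.72). At a q-value of 0.01 the glycoalkaloid and precursor pathway lists no longer passed at 47 DPA (Fisher's exact test, adjusted p = 0.144 and 0.0980).

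At 54 DPA many photosynthesis genes and several ethylene synthesis genes were higher in n3122, and many genes of ripening, softening and carotenoid synthesis were lower. RBCS2 had 0.527 FPKM in M82 and 84.6 in n3122 (log2 fold change 5.81) and CAB7 5.47 and 290.0 (5.49), with q-values of 0.00295 and 0.000377 in the authors' deposited table. PL was lower at 2166 against 6.40 FPKM (-8.19), CEL2 at 537 against 1.14 (-7.98), RIN at 977 against 28.3 (-5.06) and PSY1 at 3034 against 129 (-4.55).

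Of 19 tested genes of chlorophyll metabolism and photosynthesis, 12 were higher and 4 lower at 54 DPA, with 14 higher and 4 lower adjusted over the list alone (Fisher's exact test, two-sided, adjusted p = 0.000183 for higher). The 4 lower were again SGR1 (622 FPKM in M82 and 258 in n3122), PAO, PPH and APRR2, and CAB8 was among those higher (log2 fold change 4.37). Of 9 glycoalkaloid genes, 5 were higher and 1, GAME31, lower, with 6 higher and 1 lower adjusted over the list alone (Fisher's exact test, adjusted p = 0.0462 for higher). GAME12 had 0.762 FPKM in M82 and 38.3 in n3122, GAME11 3.01 and 42.0, and GAME1 0.418 and 3.25. With checked names alone this list no longer passed (Fisher's exact test, adjusted p = 0.0851), nor did it at a q-value of 0.01 (0.0867) or with a minimum log2 fold change of 1 (0.0605).

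Ethylene synthesis genes were mixed at 54 DPA. Of 11 tested, 6 were higher and 3 lower, with 7 higher and 3 lower adjusted over the list alone (Fisher's exact test, adjusted p = 0.0277 for higher, 0.149 at a q-value of 0.01). Those higher included ACS6, ACO5 (2.94 FPKM in M82 and 18.5 in n3122) and ACO6 (14.6 and 62.4), and those lower were ACS2 (310.5 and 21.1), ACS4 (122 and 10.5) and ACO3. ACO1 was not called, at 1489 and 1238 FPKM. Of 15 genes of ethylene perception and signalling, 8 were lower and 1 higher, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.000745), among them NR at 257 and 32.0 FPKM and EBF1 at 189.6 and 37.5.

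Of 16 ripening regulators and ethylene-responsive genes, 11 were lower and 1 higher at 54 DPA, with 11 lower and 2 higher adjusted over the list alone (Fisher's exact test, adjusted p = 4.03e-06). NOR had 475 FPKM in M82 and 142 in n3122, E8 4274 and 356, and E4 2477 and 45.6. Of 14 cell wall genes, 8 were lower and 2 higher, with 9 lower and 2 higher adjusted over the list alone (Fisher's exact test, adjusted p = 0.000432). PG2A had 320.1 and 28.9 FPKM and EXP1 1182 and 49.1. Of 6 carotenoid genes up to lycopene, 4 were lower and none higher, with 5 lower adjusted over the list alone (Fisher's exact test, adjusted p = 0.0119, 0.125 with a minimum log2 fold change of 1). Z-ISO and ZDS had log2 fold changes of -5.20 and -0.80. PDS, called lower at 47 DPA, was not called, at 79.9 and 72.7 FPKM. Of 11 aroma and sugar genes, 6 were lower and 3 higher, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.00392), with LOXC at 543 and 4.92 FPKM, AAT1 at 2117 and 125 and TIV1 at 2886 and 567.

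The remaining lists did not pass at 54 DPA at a q-value of 0.05. In the precursor pathway 3 of 11 were higher and 4 lower, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.0967 for lower, but 0.0292 at a q-value of 0.01), IDI2 being higher (log2 fold change 1.49) and GGPS2 and GGPS3 lower (-3.42 and -1.01). Of 16 phenylpropanoid and flavonoid genes, 2 were higher and 4 lower, the same adjusted over the list alone, with CHS1 (54.8 FPKM in M82 and 0.554 in n3122) and CHS2 (95.7 and 14.3) lower and the chalcone isomerase gene CHI higher (log2 fold change 1.42). Of 8 cyclization and xanthophyll genes, ZEP and CYP97A29 were higher (log2 fold changes 1.20 and 0.74) and CRTRB1 lower (-0.95), the same numbers adjusted over the list alone. Of 7 cleavage and ABA genes, 3 were higher and 1 lower, with 4 higher and 1 lower adjusted over the list alone; NCED1, which makes the ABA precursor, was higher at 80.1 against 158 FPKM, as were CCD4B and CYP707A1 (log2 fold changes 3.14 and 2.62), and CYP707A2 was lower (-1.04). Of 6 cuticle and epidermis genes, CD1 and CD2 were higher (log2 fold changes 3.72 and 0.74), 2 also adjusted over the list alone (Fisher's exact test, adjusted p = 0.570).

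The comparison of n3122 at 60 DPA with M82 at 47 DPA sets older mutant fruit beside younger wild-type fruit, so genotype and age differ together. Some ripening genes called at 47 DPA were not called here, and others were far lower. ACS4 had 101.3 FPKM in M82 and 144 in n3122, MAN4 1090.4 and 1694, LOXC 378 and 275, and AAT1 1792 and 1077, with q-values of 0.268, 0.440, 0.451 and 0.350 in the authors' deposited table. E4 was lower at 4486 against 48.2 FPKM (log2 fold change -6.51), PL at 1760.4 against 36.9 (-5.54) and NR at 269 against 41.2 (-2.68). RIN was also lower, at 704 against 364 FPKM (-0.95, q-value 0.0464 in the authors' deposited table).

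Of 16 ripening regulators and ethylene-responsive genes, 9 were lower and none higher in this comparison, with 10 lower adjusted over the list alone (Fisher's exact test, two-sided, adjusted p = 6.44e-06). NOR had 604 FPKM in M82 and 281 in n3122, E8 5048 and 1112, AP2A 345 and 109, and CNR 251 and 56.8. Of 15 genes of ethylene perception and signalling, 8 were lower and 1 higher, the same adjusted over the list alone (Fisher's exact test, adjusted p = 3.27e-05): EIN2, NR, ETR4 (287 and 49.4 FPKM), ETR6 (39.9 and 4.77), ETR7, CTR1, EIL4 and EBF1 (153 and 21.1). Of 10 ethylene synthesis genes, 4 were lower and 1 higher, with 5 lower and 3 higher adjusted over the list alone (Fisher's exact test, adjusted p = 0.0162), ACS2 at 354 and 97.7 FPKM and ACO1 at 2547 and 737 among those lower. ACO3 was lower and ACS6 higher, with log2 fold changes of -2.74 and 2.37. Of 14 cell wall genes, 6 were lower and 3 higher, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.00168 for lower), with PG2A at 3458 and 794 FPKM and CEL2 at 255 and 6.31. The median log2 fold change of the cell wall list was -0.18, above that of 60.2% of random lists of like expression. The cell wall list as a whole was thus not lower than such genes, though single members were. For ethylene synthesis the median was -0.42, above that of 6.59% of random lists.

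Of 16 phenylpropanoid and flavonoid genes, 9 were lower and none higher, with 11 lower adjusted over the list alone (Fisher's exact test, adjusted p = 6.44e-06), among them CHS1 at 326 FPKM in M82 and 27.6 in n3122, CHIL (log2 fold change -2.16) and PALc (-2.23). Of 11 precursor pathway genes, 4 were lower and none higher, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.0228, and 0.0797 with checked names alone), GGPS2, DXS1 and CMK among them with log2 fold changes of -3.29, -1.31 and -1.07. Carotenoid genes up to lycopene were lower in 2 of 6, PSY1 (4102 and 644 FPKM) and Z-ISO (2087 and 79.0), 2 also adjusted over the list alone, and the list did not pass (Fisher's exact test, adjusted p = 0.189). Of 10 aroma and sugar genes, 3 were lower and 1, LOXA, higher, with 4 lower and 1 higher adjusted over the list alone (Fisher's exact test, adjusted p = 0.0967 for lower, but 0.0292 at a q-value of 0.01 and 0.0438 with a minimum log2 fold change of 1). LOXA had a log2 fold change of 2.48, HPL -2.28 and AADC1A -1.57.

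Of 20 genes of chlorophyll metabolism and photosynthesis, 6 were higher and 2 lower, with 6 higher and 3 lower adjusted over the list alone (Fisher's exact test, adjusted p = 0.0162 for higher, 0.167 at a q-value of 0.01 and 0.0960 with a minimum log2 fold change of 1). RBCS2 had 7.52 FPKM in M82 and 42.6 in n3122 and RBCS1 4.99 and 16.8, while SGR1 (849 and 394) and APRR2 (log2 fold change -1.92) were lower. Of 7 cleavage and ABA genes, 3 were higher and 1 lower, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.0474 for higher, 0.240 with checked names alone and 0.0502 with the filter of 1 FPKM). CYP707A1 was higher at 4.25 against 17.1 FPKM, CCD4B at 3.09 against 10.9, and CYP707A2 lower at 115 against 9.40. The lists of glycoalkaloid genes (2 of 9 higher), of cyclization and xanthophyll genes (1 higher and 1 lower of 8) and of cuticle and epidermis (2 of 6 higher) did not pass; adjusted over the list alone, 2 were higher, 2 higher and 2 lower, and 3 higher. CD1 had 0.463 FPKM in M82 and 5.67 in n3122, and the log2 fold changes of CD2, GAME4, GAME12, ZEP and CRTRB2 were 0.87, 1.40, 0.98, 1.07 and -1.65.

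**Figure D3:**
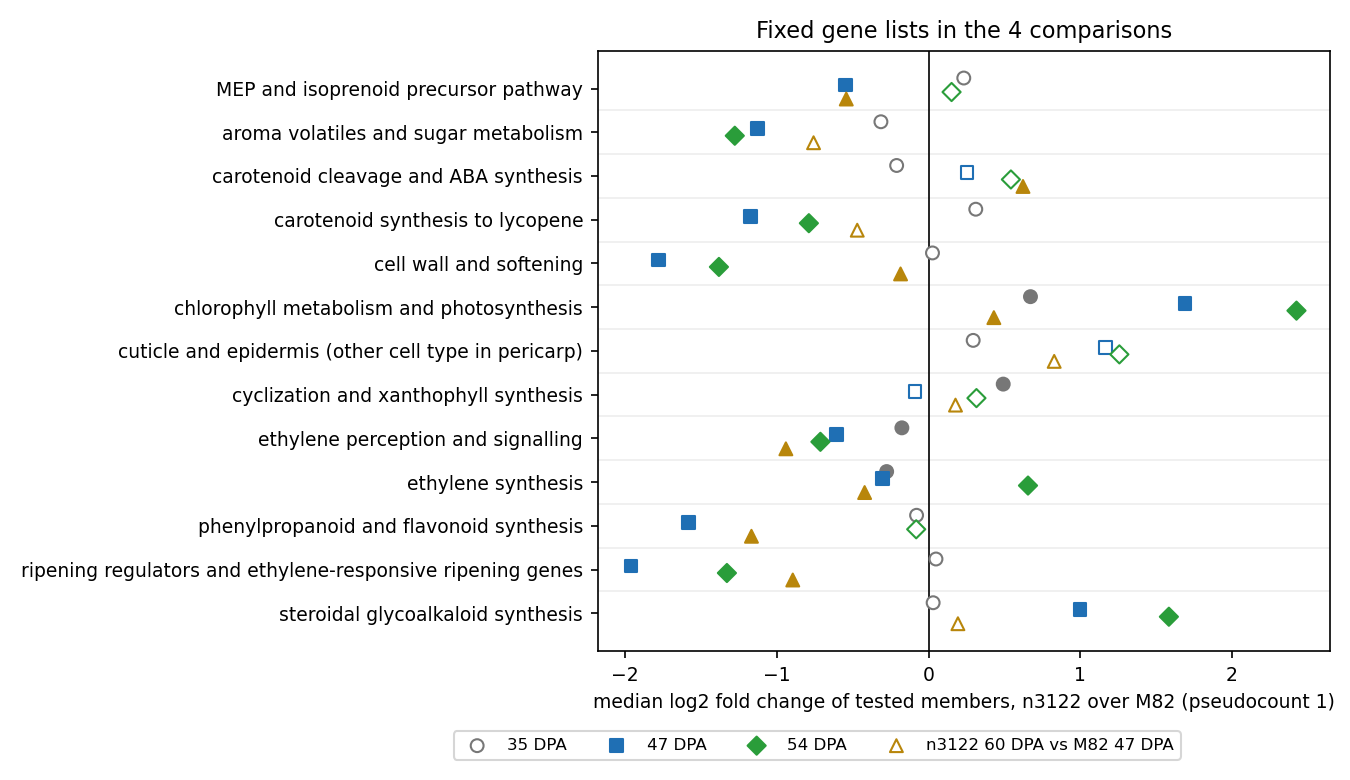
Median log2 fold change (n3122 over M82, pseudocount 1 FPKM) of the tested members of each of the 13 lists in the 4 comparisons, marked by shape and colour; filled points passed the list test in either direction and open points did not. The ripening regulator list lies at -1.96 at 47 DPA, -1.33 at 54 DPA and -0.90 for n3122 at 60 DPA against M82 at 47 DPA, and the photosynthesis list at 0.67, 1.69, 2.43 and 0.43 across the 4 comparisons.

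**Figure D4:**
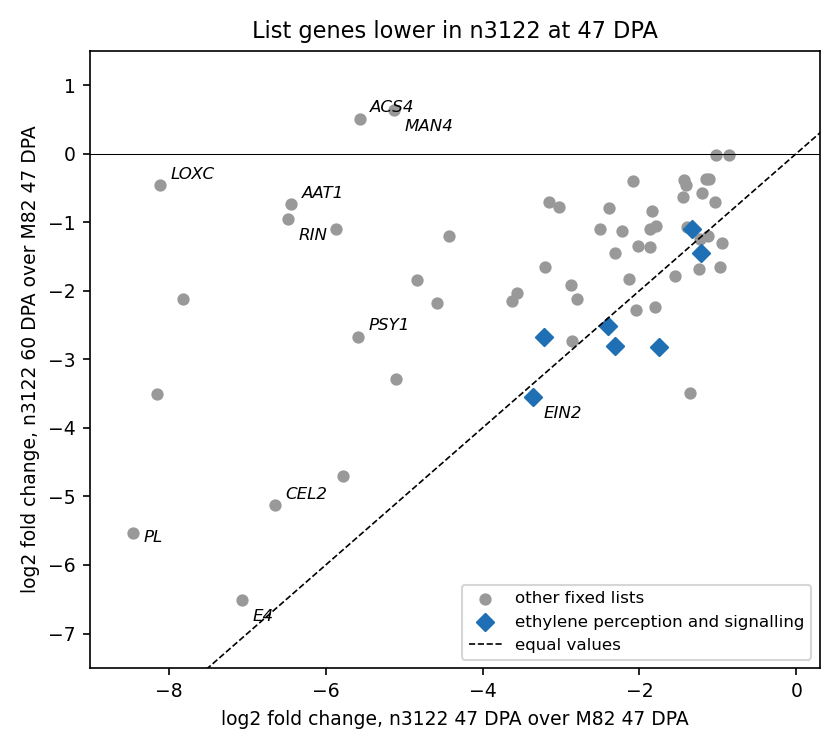
Log2 fold change of n3122 at 60 DPA over M82 at 47 DPA (vertical) against that of n3122 at 47 DPA over M82 at 47 DPA (horizontal) for the list genes lower at 47 DPA with at least 10 FPKM in M82; the dashed line marks equal values and diamonds are genes of ethylene perception and signalling. ACS4 lies at -5.57 and 0.51, and E4 at -7.07 and -6.51.

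Many genes were called in more than one comparison. Of genes tested both at 47 and at 54 DPA, 2023 were higher in both (461 if the calls were independent) and 1215 were lower in both (209 if independent). Between 35 and 47 DPA, 191 were higher in both (48.1 if independent) and 42 lower in both (22.7 if independent), while 63 genes lower at 35 DPA were higher at 47 DPA (33.5 if independent) and 31 higher at 35 DPA were lower at 47 DPA (32.7 if independent). Between 35 and 54 DPA, 221 were higher in both (63.5 if independent) and 111 lower in both (25.9 if independent). The comparisons at 47 DPA and of n3122 at 60 DPA with M82 at 47 DPA shared 1027 genes higher (191 if independent) and 815 lower (133 if independent). Both rest on the same M82 libraries, so part of this excess may come from the shared controls, and no simulation was possible without replicate values. In all 4 comparisons 104 genes were higher, among them RBCS2, ZEP, PSBP and RCA, and 35 lower, among them EIN2, ETR6, EBF1 and E4. Independent calls would give 0.658 higher and 0.169 lower, and 3.48 and 1.08 with the overlap of the comparisons that share M82 libraries kept as found.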

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

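The tests of the genes near EIN2, of EIN2 and of the genes at 54 DPA relative to the median, of the numbers that fell and rose in M82, of the starting drop and of the ethylene perception genes were chosen only after the result was seen.

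A few list genes were called in opposite directions at different ages, and for none of them was the difference between ages tested. PDS was higher in n3122 at 35 DPA and lower at 47 DPA, a change of -1.46 in log2 fold change. SGR1 did the same from 35 to 47 DPA (-2.58) and to 54 DPA (-1.98), as did CHS2 (-5.08 to 47 DPA and -3.32 to 54 DPA) and MAN4 (-7.59 from 35 to 47 DPA). ACO5 was lower at 35 DPA and higher at 54 DPA (a change of 3.47), and ACO6 was lower at 35 and 47 DPA and higher at 54 DPA (2.71 and 3.06). AADC1A was lower at 35 DPA and higher at 47 DPA (2.17), and LIN6 was higher at 47 DPA and lower at 54 DPA (-2.45). Across all genes, 94 were called opposite ways at 35 and 47 DPA, 75 at 35 and 54 DPA and 30 at 47 and 54 DPA.

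EIN2 was lower in n3122 in all 4 comparisons, with log2 fold changes from -3.36 to -3.55. Loss of a segment that also covers nearby genes would lower these too, but the 6 measured genes among the 5 nearest identifiers on each side had a median of -0.19 in the lowest of the 4 comparisons, with 1 of the 6 called lower there and none in the other comparisons. Lower scaling of n3122 as a whole would move all genes alike, but EIN2 lay at least 3.33 log2 units below the median of all genes (-3.33 in the comparison where it lay closest). A change at EIN2 itself may account for the drop, as a hypothesis; the tables hold no sequence to test it, and the labels name no mutated gene.

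At 54 DPA more genes were higher (3409) than lower (2165) in n3122. The median fold change was -0.053, which decides nothing here, since the authors' scaling may set it near 0. Scaling, or a few abundant transcripts taking a larger share in M82, would move all genes alike, yet of the genes at least 1 log2 unit from the median, 1903 lay above it and 877 below (68.5% above, 95% interval 66.7 to 70.2, with genes taken as independent), which argues against these as the whole cause. Of the genes higher at 54 DPA, 50.3% had fallen by at least 1 log2 unit in M82 from 35 to 47 DPA, in libraries outside that comparison, against 6.37% of genes not called (odds ratio 14.9, 95% interval 13.5 to 16.4). Of those lower, 56.1% had risen, against 6.64% (odds ratio 18.0), so these shares do not address why more genes were higher than lower. From 35 to 47 DPA 2468 genes fell and 2099 rose by this much in M82, a ratio of 1.18 against 1.57 for the calls at 54 DPA. The first ratio counts genes by size of change and the second by q-value, so they are not like counts. By size of change, the numbers at 54 DPA were 1903 and 877, as given above. No n3122 level from another age entered this test, so whether n3122 kept its own levels was not tested. Genes ranked much alike in M82 at 47 and 54 DPA (Spearman correlation 0.961) and in both genotypes at 35 DPA (0.977). The calls at 54 DPA may thus partly follow from the changes in M82 alone. That n3122 keeps levels of an earlier M82 age stays a hypothesis for both directions, and its part in the balance stays open. These M82 levels also come from tables scaled separately. Whether fruits of equal age had reached equal stages is open.

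Of 1564 genes lower in n3122 at 47 DPA with at least 10 FPKM in M82, 727 (46.5%) were still lower at 60 DPA against the same M82 group, 14 were higher and 823 were not called. A lost call does not show a return toward M82. ADH2, for one, was called lower at 47 DPA at -1.13 and was not called at 60 DPA at -1.20. Scaling of the table at 60 DPA would move all genes alike. The 1564 genes moved by 0.44 at the median. The 8223 genes with at least 10 FPKM in M82 called in neither comparison moved by 0.066. Genes called in neither are chosen for little change, so they cannot by themselves exclude scaling. The 1564 genes were picked by their low values at 47 DPA, so part of their move may follow from that choice. The 6 genes of ethylene perception other than EIN2 moved by 1.01 less than genes with a like starting drop (a difference of -1.01): all 6 were still lower at 60 DPA, and their mean change was -0.19 against 0.82. These genes may return less than other genes, as a hypothesis (permutation test, two-sided, 9 lists, adjusted p = 0.0412), but without ETR6 the unadjusted p was 0.0425, which the 9 lists would not leave past 0.05. The starting size of the drop was weighed by this same comparison with genes of a like drop (permutation test, unadjusted p = 0.00916, at most 0.0425 without any one gene). Since the list was picked after the result was seen, the comparison cannot tell the starting drop from chance among the 9 lists. Both stay open. Age and genotype differ together here, which stays open.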

How the results depend on the processing

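The lists of checked names were an alternative chosen after the result was seen; all others were fixed before. No paired analysis was possible because the tables hold one value per group. For the same reason other count-based tests and leaving out each replicate were not run. Setting the median to 0 and a pseudocount of 0.1 leave the authors' calls as they are by construction, so they test nothing there, and the filter of 1 FPKM kept the 16 counts it was run on within 1.5 times. No direction reversed. Sequencing depth is unknown, so its limit cannot be stated.

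At a q-value of 0.01 fewer genes passed, which follows from the stricter threshold. Called genes numbered 338 at 35 DPA (199 higher, 139 lower), 2920 at 47 DPA (1169 lower), 1391 lower at 54 DPA, and 1620 for n3122 at 60 DPA against M82 at 47 DPA (833 higher, 787 lower). Lists passing at 35 DPA numbered 2. Overlaps fell to 102 higher and 20 lower for 35 and 47 DPA, 769 lower for 47 and 54 DPA, and 564 higher and 490 lower for 47 DPA and the comparison at 60 DPA, with 44 higher and 14 lower in all 4. Of 150 single gene results, some never called, 23 no longer passed, RIN, NOR, PSY1, ACO1, E8 and SGR1 at 60 DPA among them.

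With a minimum log2 fold change of 1, called genes numbered 288 at 35 DPA (156 higher, 132 lower). At 47 DPA they numbered 3190 (1961 higher, 1229 lower) and at 54 DPA 3291 (2251 higher, 1040 lower). Lower genes were thus fewer at 54 than at 47 DPA with this minimum, unlike without it. The share of higher calls at 54 DPA was 68.4% against 61.2%. Lists passing at 35 DPA numbered 2. Overlaps were 83 higher and 20 lower for 35 and 47 DPA, 662 lower for 47 and 54 DPA and 543 lower for 47 DPA and the comparison at 60 DPA, with 41 higher and 17 lower in all 4. The other table for M82 at 47 DPA gave a median of 16.8 FPKM against 17.6, the constant ratio between both tables. Single list tests lost their call in 7 cases at a q-value of 0.01 and in 5 with the minimum fold change. With checked names alone 3 lost it, and with the filter 1. At a q-value of 0.01, 2 gained a call, and with the minimum fold change 1 did. Only tests that had passed could lose a call. For lower and higher genes these numbered 2 and 2 at 35 DPA, 8 and 2 at 47 DPA, and 5 and 3 at 54 DPA. For n3122 at 60 DPA against M82 at 47 DPA they numbered 6 and 2.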

Other observations

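The tests on single lists and that of genes lower at 54 DPA were chosen after the result was seen.

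Across the 19867 genes compared, n3122 at 47 DPA ranked closest to M82 at 35 DPA (Spearman correlation across genes 0.936, against 0.883 with M82 at 47 DPA and 0.856 at 54 DPA). The same held for n3122 at 54 DPA (0.919, 0.896 and 0.873), while n3122 at 60 DPA ranked closest to M82 at 47 DPA (0.922, against 0.892 at 35 DPA and 0.909 at 54 DPA). At 35 DPA both genotypes correlated at 0.977. Within M82, 35 DPA correlated at 0.8485 with 47 DPA and at 0.8075 with 54 DPA. Thus n3122 at 47 and 54 DPA ranked closer to M82 of equal age than M82 at 35 DPA did. Genes are not independent replicates, and no error stands behind these values.

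The genes of aroma volatiles and sugar metabolism lower at 47 DPA moved by more than genes with a like starting drop by 60 DPA. Of the 6, LOXB, LOXC, HPL, ADH2, AAT1 and TIV1, only HPL was still called lower, but ADH2, no longer called, had log2 fold changes of -1.13 at 47 DPA and -1.20 at 60 DPA, so neither of these 2 moved toward M82. The other 4 did, and the mean log2 fold change moved by 2.96, which is 1.76 more than that of genes matched on that drop (permutation test, two-sided, 9 lists, adjusted p = 0.0412). Without LOXC the unadjusted p was 0.110, so the result rests on that gene. Of 8 softening genes, 6 were still lower, among them PL and CEL2, and their mean moved by 2.99 (permutation test, adjusted p = 0.153). The 10 ripening regulators moved by 1.51, with 8 still lower (permutation test, adjusted p = 0.781). The permutation test was tested on simulated data: with 1500 genes and 6 shifted by -1.5, it passed in 40 of 40 rounds, and with no shift in 2 of 40. The planted shift was larger than the difference of -1.01 found for the ethylene perception genes. Simulated genes changed independently and the p-values were not adjusted. These rounds therefore do not give the power or error rate of the tests reported.

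Of genes lower in n3122 at 54 DPA, 56.1% had risen by at least 1 log2 unit in M82 from 35 to 47 DPA, against 6.64% of genes not called (odds ratio 18.0, 95% interval 16.1 to 20.1). Identical high values also occurred: 18 of 1652 genes at or above 100 FPKM in n3122 at 54 DPA shared an exact value with another gene, the largest being 119477 FPKM. Of these, 14 lay under 1000 FPKM, where rounding of the values alone would give about 12.2. In M82 at 54 DPA, 26 genes under 1000 FPKM shared a value, against about 12.5 from rounding, so rounding may not account for all of them. For M82 at 47 DPA the numbers were 18 against 12.7 in the comparison at 47 DPA. In the comparison with n3122 at 60 DPA they were 10 against 11.9. In n3122 at 35 DPA the number was also under that from rounding, 10 against 11.9.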
